A study of Mus musculus with 4 samples.

How the data were processed

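Total RNA of stomachs from mouse embryos at embryonic day 15.5 was depleted of ribosomal RNA by an RNase H method, reverse transcribed with random hexamers and sequenced as paired reads on an Illumina instrument, per the labels' protocols. The submitters' processing notes name FastQC 0.10, Trimmomatic 0.33, Salmon 1.8.0 and edgeR, and the builds GRCm38 and mm10, without giving their roles or order. The transcript index, the annotation release, the strand setting and the step from transcripts to genes are not given in the sources used here. The deposited table holds estimated counts per Ensembl gene, not scaled to depth; between 28.5% and 29.1% of the values in a column were not whole numbers.

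Samples were grouped by the genotype field of the labels. Fgf9_null is Fgf9LacZ/LacZ and Fgf9_het is Fgf9LacZ/+. The sample titles abbreviate the latter group as WT, and the genotype field was followed. Replicate numbers 2 and 3 were taken from the titles. Each of the 4 samples was matched to a column of the table by its title. The table has 2 further columns of values with no name. They were seen when the table was inspected, but no label assigns them to a sample, so they entered no computation reported here. Whether each name in the header stands over the column it belongs to is not settled by the sources used here. The sources do not say whether a sample came from 1 embryo or from several.

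The table holds 51098 genes, of which 50870 were found by identifier in GENCODE M21, the annotation of GRCm38 used for coordinates and transcript sequences. Of the genes in that annotation, 4666 have no row in the table used here. A symbol was repeated in 96 rows, and the row with the highest level was used for levels. Counts of genes that share sequence with a near-identical copy, such as the 7SL RNA and haemoglobin genes, depend on how the authors' counting divided their reads. Column totals were 19537211, 22713416, 19269851 and 22425865 for Fgf9_null replicates 2 and 3 and Fgf9_het replicates 2 and 3. At these depths 1 count was worth 0.0440 to 0.0519 CPM. Poisson intervals (exact, 95%) and the floor of 3 counts cover counting error only.

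Columns were checked for shared libraries with a chi-square statistic over genes with a summed count of at least 10, divided by its degrees of freedom. It was computed with and without the 4 genes that had an unadjusted edgeR p under 0.05, a set chosen after the values were seen. The statistic was tested on simulated data, where separate draws of reads gave 1.00 over 21326 genes. Without the 4 genes, same-numbered columns of the 2 labels fell far below that value. The replicate numbers therefore pair columns of 1 library, and the deviations of same-numbered columns from their group means correlated at 0.998 across genes. The mean of the 2 columns of a library was used as 1 sample for all levels, which are given as mean CPM ± SD over n = 2 libraries.

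The comparison of the labels was still run as planned. Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr by group, quasi-likelihood F test, Benjamini-Hochberg adjustment, threshold 0.05), which kept 19987 genes. Adjusted p-values and log2 folds with standard errors come from this fit unless another tool is named. The p-values measure only the spread between these columns, which is not the spread between embryos. Gene lists were tested with camera in limma 3.58.1, on log2 CPM with a prior count of 2, a preset correlation of 0.01 and at least 5 tested members. On simulated groups of 2 against 2 over 51098 genes, edgeR recovered 86% of 100 genes changed by 2-fold and 100% of 100 changed by 4-fold, with 9 false calls. DESeq2 1.42.0 recovered 79% and 99%, with 10 false calls. camera called only the 1 list that was raised in the simulation. All simulated genes had the same dispersion of 0.0161, and the 2-fold and 4-fold changes were put only on well-counted genes. The simulated columns were 4 separate libraries, whereas the columns here hold 2 libraries, each present under both labels. The recovery rates therefore do not carry over to the comparison of the labels. Genes were simulated independently, so the simulation does not show error control where genes of a list vary together.

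The 45 gene lists, with 729 different symbols, and the rule for named genes were fixed before the data were examined; 12 symbols have no row. The rule took Fgf9, then up to 15 genes in each direction among edgeR calls with a mean of at least 2 CPM, groups that did not overlap and a symbol that was not a predicted gene. For each list it took the 4 called members with the smallest p or, where none was called, the 2 members with the highest mean CPM. As edgeR called no gene, it yielded Fgf9 and the 2 most abundant members of each list; not all of these are named in the text, and genes named beyond them are said to be so.

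Differences between library 2 and library 3 were described without a test, for list members with a mean of at least 1 CPM and lists with at least 5 of them. Ratios were formed after adding 0.1 CPM. The median of a list was set against 10000 random lists of the same size matched on mean level. Sequence shared between genes was searched as stretches of 31 bases on the transcript strand, and the search was tested on made-up sequences.

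Alternatives planned before the data were examined were other normalizations (RLE, upper quartile), other count filters, DESeq2, limma-voom and the legacy quasi-likelihood method. Also planned were the replicate number as a block, each column left out in turn, other thresholds, an estimated correlation and fry. A further planned setting left out haemoglobin and mitochondrial genes and the non-coding genes Rn7sk, Rmrp, Rpph1, Neat1, Malat1 and Snhg1. It kept Gm26917 and Rn7s1. Levels from the columns of a single label and levels without 6 structured and ribosomal RNA genes were added after seeing the data. Scripts ran under Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.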

Results

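RNA sequencing was used to measure gene expression in the stomachs of mouse embryos at E15.5 (embryonic day). The stated comparison set stomachs homozygous for the Fgf9LacZ allele against stomachs carrying that allele beside a normal copy. Fgf9 encodes a secreted fibroblast growth factor. The 4 samples fell into 2 groups of 2, called Fgf9_null and Fgf9_het here, and in both groups the samples were numbered 2 and 3. The estimated counts summed to 19537211 and 22713416 in the Fgf9_null columns and to 19269851 and 22425865 in the Fgf9_het columns. A count of 3, taken as the detection floor, corresponded to 0.132 to 0.156 CPM (the count scaled to the column total).

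Fgf9 itself had the same number of reads under both genotype labels. The gene (ENSMUSG00000021974, GRCm38 chromosome 14, 58070547 to 58112720, plus strand, protein coding) had 133 reads in replicate 2 and 131 reads in replicate 3 of Fgf9_null, and again 133 and 131 reads in Fgf9_het. The exact Poisson 95% intervals, which cover counting error only, were 111 to 158 and 110 to 155 reads. The level was 6.81 and 5.77 CPM under the Fgf9_null label and 6.90 and 5.84 CPM under the Fgf9_het label. The count does not check the genotype, because reads from parts of Fgf9 that the LacZ allele keeps may be included.

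The match extended from Fgf9 to nearly every gene. Among genes with a summed count of at least 10, 60.8% of 21487 genes had counts equal within 0.001 reads in the replicate 2 columns of the 2 labels, and 59.1% of 21788 genes did in the replicate 3 columns. Over all these genes, the chi-square statistic per degree of freedom between same-numbered columns was 4.46 for replicate 2 and 4.64 for replicate 3. With the 4 genes of unadjusted edgeR p under 0.05 left out, it was 0.000792 for replicate 2 and 0.00385 for replicate 3. Simulated separate draws of reads gave 1.00, and columns of different number gave 5.49 to 5.50. Outside the 4 genes, the columns of the same number thus differed by less than the sampling noise, and they were counted as 1 sample. The 4 columns hold 2 independent libraries, called library 2 and library 3 here, each present under both genotype labels. The Fgf9_null against Fgf9_het contrast therefore compares each library with itself, and what follows does not resolve which genotype either library had.

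**Figure D1:**
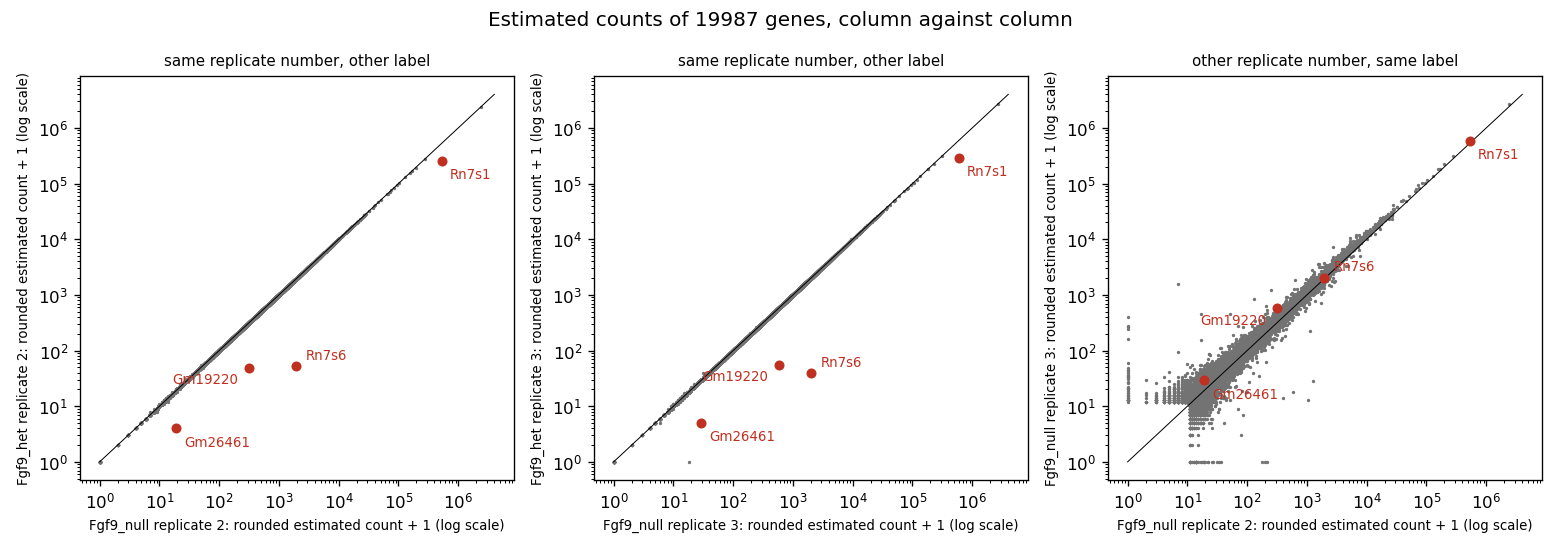
Rounded estimated counts plus 1 of 19987 genes, column against column, on log axes; each point is a gene and the line marks equal counts. Same-numbered columns of the 2 genotype labels lie on the line apart from Rn7s1, Rn7s6, Gm19220 and Gm26461 (red) and a few low-count genes, while replicates 2 and 3 of Fgf9_null scatter around it.

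The first comparison asked which genes differ between Fgf9_null and Fgf9_het stomachs. The genes that stood apart between the labels were small structured RNAs and a pseudogene, with no gene of a gastric cell type among them. Rn7s1, a gene of the 7SL RNA of the signal recognition particle (ENSMUSG00000099021, chromosome 12, 69159295 to 69159594), had 529306 and 588969 reads under the Fgf9_null label and 255292 and 291630 reads under the Fgf9_het label. Rn7s6 (ENSMUSG00000092746, chromosome 6, 69516339 to 69516629), annotated as a miscellaneous RNA, had 1943 and 2021 reads against 51 and 38. The processed pseudogene Gm19220 had 319 and 578 reads against 48 and 55, and the miscellaneous RNA Gm26461 had 18 and 28 reads against 3 and 4. These 4 genes were named after their values were seen.

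edgeR's quasi-likelihood test called 0 of 19987 genes at an adjusted p under 0.05, and 4 genes, those named above, had an unadjusted p under 0.05. The log2 fold of Fgf9_null over Fgf9_het was 5.47 (SE 0.179) for Rn7s6 and 1.03 (SE 0.0367) for Rn7s1, each at an edgeR adjusted p of 0.571. It was 3.11 (SE 0.351) for Gm19220 and 2.67 (SE 0.322) for Gm26461, each at an edgeR adjusted p of 1. DESeq2 called 3 genes, Rn7s6, Rn7s1 and Gm19220, and limma-voom called 0. With the replicate number as a block, edgeR called 1178 genes, 200 higher and 978 lower under the Fgf9_null label, with a median absolute log2 fold of 0.00597; 5 of them passed 1.5-fold. Because both columns of a block hold the same library, none of these counts measures an effect of Fgf9.

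The second comparison asked whether groups of genes differ between the labels. Members of the FGF and ERK response, Hedgehog, smooth muscle, gastric epithelial, proliferation and all other tested lists had nearly the same level under both labels, with a largest absolute log2 fold of 0.0388 for any list member. camera called 0 of 44 lists, with a smallest adjusted p of 0.995, and it also called 0 lists with an estimated correlation. edgeR called 0 list members over all genes and 0 members adjusted over the list alone. The list of lung and oesophagus genes had fewer than 5 tested members and was not tested. With any 1 of the 4 columns left out, camera called 7 lists, because the remaining columns then hold library 2 and library 3 in unequal numbers.

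With genotype set aside, the 2 libraries describe gene expression of the embryonic stomach. Each label names both libraries as replicates of 1 group, and levels are given as mean CPM ± SD over n = 2 libraries. CPM was not scaled to transcript length, so a comparison between genes can reflect length as well as abundance. Whether the libraries share a genotype was not tested, so the SD may include a difference between genotypes. At least 1 CPM was reached in both libraries by 16712 genes. Where a paragraph names more than the most abundant pair of a list, the further genes were chosen after their values were seen.

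Connective tissue and smooth muscle genes were among those with the highest CPM. The collagen genes Col1a1 and Col3a1 stood at 5284 ± 104 and 3794 ± 148 CPM, and the 20 extracellular matrix genes together made up 20440 ± 164 CPM. The contractile genes Myh11 (smooth muscle myosin) and Acta2 (smooth muscle actin) reached 2165 ± 119 and 1663 ± 2.0 CPM, and all 18 smooth muscle genes exceeded 1 CPM in both libraries. Among mesenchymal and regional transcription factors, Meis2 and Meis1 stood at 174 ± 3.46 and 169 ± 4.14 CPM. Barx1, a transcription factor of the stomach mesenchyme, reached 133 ± 4.73 CPM. Of the pyloric list, the nuclear receptor genes Nr2f2 and Nr2f1 had 144 ± 6.02 and 98.4 ± 1.30 CPM, while the gastrin gene Gast had 1.10 ± 0.0498 CPM.

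Epithelial genes spanned the glandular stomach and the squamous forestomach. The keratin gene Krt8 and the E-cadherin gene Cdh1 stood at 581 ± 9.75 and 389 ± 3.32 CPM. Cym, which encodes the milk-clotting protease chymosin, reached 4692 ± 269 CPM and was far above Muc6, a gland mucin gene, at 228 ± 5.26 CPM. The surface mucous genes Muc1 and Muc5ac had 166 ± 13.2 and 164 ± 2.80 CPM, whereas the surface mucous gene Gkn1 had 0.468 ± 0.286 CPM. Parietal cell genes were at intermediate levels, with Clic6 at 66.6 ± 2.60 and Kcnj15 at 54.6 ± 0.376 CPM. Both subunits of the gastric proton pump were expressed, Atp4a at 29.4 ± 8.73 and Atp4b at 29.9 ± 2.68 CPM. The squamous keratin genes Krt15 and Krt13 had 196 ± 72.9 and 110 ± 50.2 CPM. Endocrine genes were low, with Insm1 at 7.45 ± 1.20 and Chgb at 4.80 ± 0.141 CPM, and no endocrine gene reached 10 CPM in both libraries.

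**Figure D2:**
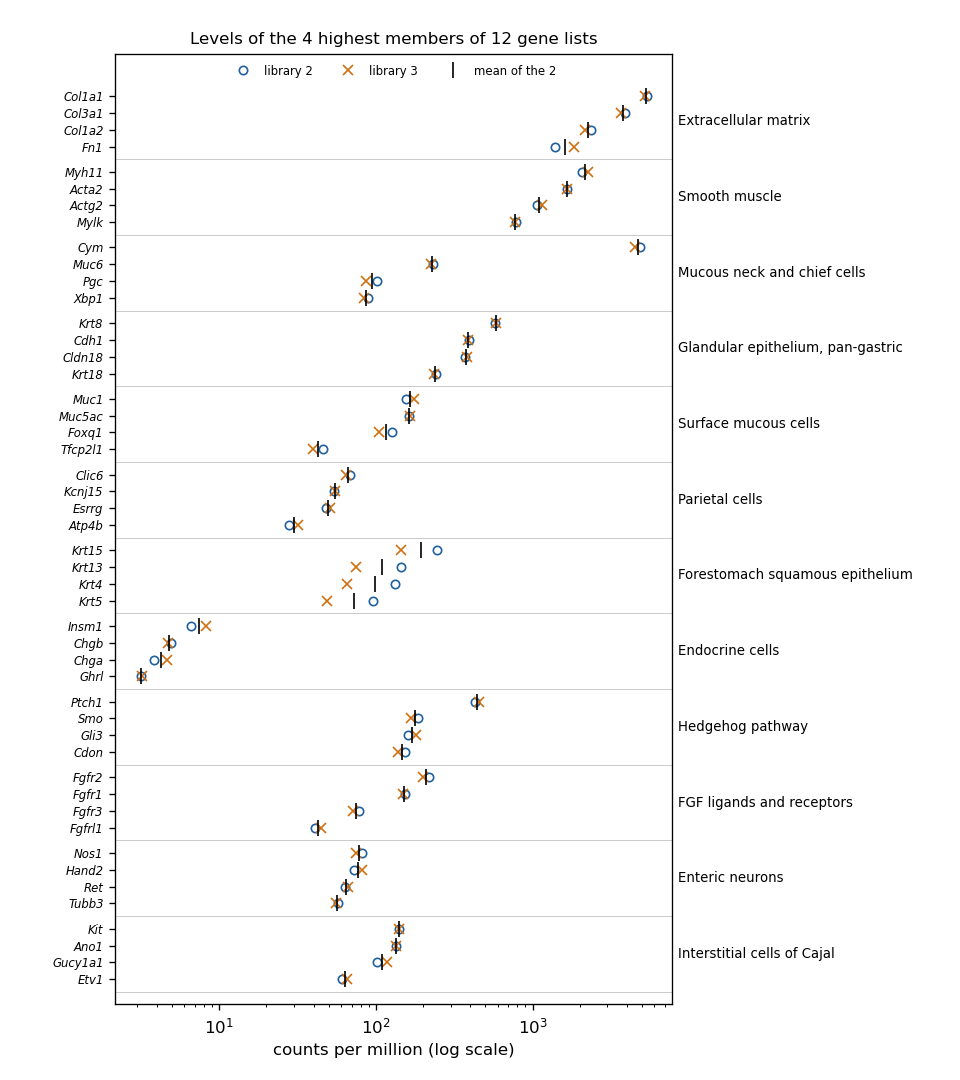
Levels of the 4 highest members of 12 gene lists, in CPM on a log axis; circles are library 2, crosses library 3 and bars the mean of the 2. Cym stands at 4692 CPM above the other gland genes, and the squamous keratin genes differ more between the libraries than the smooth muscle genes do.

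Genes of the FGF and Hedgehog pathways spanned a wide range of levels. At least 1 CPM in both libraries was reached by 15 of 23 FGF ligand and receptor genes and by 16 of 17 Hedgehog genes. The ligand genes Fgf4, Fgf15 and Fgf21 had no counts. The FGF receptor genes Fgfr2 and Fgfr1 stood at 210 ± 14.0 and 151 ± 3.28 CPM, above the ligand gene Fgf10 at 20.8 ± 3.77 CPM. All 20 FGF and ERK response genes exceeded 1 CPM in both libraries, with Ccnd1 (cyclin D1) at 121 ± 6.98 and Egr1 at 93.9 ± 44.5 CPM. In the Hedgehog list, the receptor gene Ptch1 and the signal transducer gene Smo had 443 ± 21.6 and 177 ± 12.0 CPM, and the ligand gene Ihh had 101 ± 4.20 CPM. The Wnt inhibitor genes Sfrp1 and Sfrp2 stood at 205 ± 13.3 and 73.2 ± 2.59 CPM. The BMP target genes Id1 and Id3 had 66.0 ± 8.80 and 56.3 ± 6.56 CPM. Notch2 and Notch3 stood at 357 ± 14.0 and 276 ± 13.6 CPM. In the retinoic acid list, Tgm2 and Rara had 227 ± 10.6 and 102 ± 0.613 CPM.

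Proliferation genes had high CPM, with Mki67 at 559 ± 2.47 and Top2a at 296 ± 9.85 CPM. Uhrf1 and Rrm1, expressed in S phase, stood at 146 ± 13.1 and 138 ± 6.35 CPM. The cell cycle inhibitor gene Cdkn1c had 348 ± 11.1 CPM, and the p53 target gene Zmat3 had 78.7 ± 6.87 CPM.

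Nerve, vessel and blood cell genes were present in both libraries. Nos1 and Hand2 of the enteric neuron list stood at 78.0 ± 4.69 and 77.1 ± 6.29 CPM, and Erbb3 and Ednrb of the glia and neural crest list at 159 ± 1.39 and 86.7 ± 5.12 CPM. Kit and Ano1, genes of the interstitial cells of Cajal that pace gut contraction, had 141 ± 1.08 and 135 ± 0.163 CPM. The endothelial genes Cdh5 and Kdr had 104 ± 14.1 and 78.7 ± 6.25 CPM. The haemoglobin genes Hba-a1 and Hbb-bs had 466 ± 40.3 and 414 ± 97.9 CPM, values that depend on how reads were divided among near-identical copies. The macrophage genes Csf1r and Mrc1 had 38.6 ± 1.13 and 30.4 ± 2.17 CPM. The mesothelial list was led by Krt19 at 391 ± 9.39 CPM, a keratin gene that glandular epithelium also expresses, followed by Muc16 at 49.7 ± 4.58 CPM.

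Genes of neighbouring organs were low. The summed level was 68.3 ± 22.5 CPM for 14 liver genes, 26.0 ± 1.18 CPM for 22 pancreas genes, 3.15 ± 1.31 CPM for 10 lung and oesophagus genes and 45.0 ± 0.0758 CPM for 16 intestinal genes. The 21 skeletal muscle genes summed to 109 ± 13.1 CPM.

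Non-coding RNAs took a large share of the counts. Gm26917 (chromosome 17, 39843013 to 39846341), annotated as a long non-coding RNA, held 12.0 ± 0.239% of all counts. Rn7sk held 1.42 ± 0.0262% and Gm42418 0.999 ± 0.00948%. The share of Rn7s1 depended on the label, at 2.71% and 2.59% in the Fgf9_null columns and 1.32% and 1.30% in the Fgf9_het columns. It thus lay above Rn7sk under the first label and below Rn7sk, at 1.45% and 1.41%, under the second. The rRNA gene CT010467.1 (39846353 to 39848827) beside Gm26917 held 0.635 ± 0.0508%. It spans Gm42418 (39846958 to 39848788), which is also annotated as a long non-coding RNA. The counts of Gm42418 and Gm26917 may therefore include ribosomal RNA, which was not tested. With 6 such genes left out of the library size, levels of the named genes were 1.20 to 1.21 times as high.

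The columns grouped by replicate number. The first principal component took 98.8% of the variance and separated library 2 from library 3, and the second component took 1.17%. As each library is present in 2 columns, this split was fixed in advance. The share of variance does not measure how far the libraries differ. Forestomach squamous genes were higher in library 2, with 13 of 15 members above their level in library 3 and a median of 1.42-fold. Krt13 had 145 CPM in library 2 and 74.1 CPM in library 3, and Krt15 had 247 and 144 CPM. Sprr1a, another squamous gene, was on the other side, at 16.0 CPM in library 2 and 28.8 CPM in library 3. Lymphatic endothelium genes were also higher in library 2, for 5 of 7 members, by a median of 1.27-fold. Skeletal muscle genes were higher there for 10 of 15 members, by a median of 1.20-fold. Liver, erythroid and immediate early genes were higher in library 3. All 7 liver genes in the comparison were higher there, by a median of 1.46-fold, with Apoa1 at 21.6 against 17.8 CPM. All 9 erythroid genes were higher there by a median of 1.40-fold, and 14 of 16 immediate early and heat shock genes by a median of 1.27-fold, with Egr1 at 125 against 62.5 CPM. S phase genes were higher in library 3 for 17 of 20 members, by a median of 1.10-fold.

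The libraries are 1 sample each, so these differences have no replicate check. As a description of this pair of libraries and not a test, since genes of a list can vary together, none of 10000 random lists matched on expression had a median as far toward library 2 as the squamous list, or as far toward library 3 as the liver, erythroid, immediate early and S phase lists. Other lists lay almost as far out. The BMP, hypoxia and glycolysis, blood endothelium and FGF and ERK response medians lay above 99.99%, 99.98%, 99.95% and 99.66% of random lists. Toward library 2, the mucous neck and chief cell, cell cycle inhibitor and p53 target, and Wnt medians lay above only 0.06%, 0.1% and 0.23% of them. The lymphatic endothelium and skeletal muscle medians, named before, lay less far out, above 0.45% and 1.09%. This percentile thus barely sets the lists named before apart. Over the 16712 genes at 1 CPM or more in both libraries, 649 differed by over 1.5-fold and 87 by over 2-fold, with a median of 1.08-fold.

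**Figure D3:**
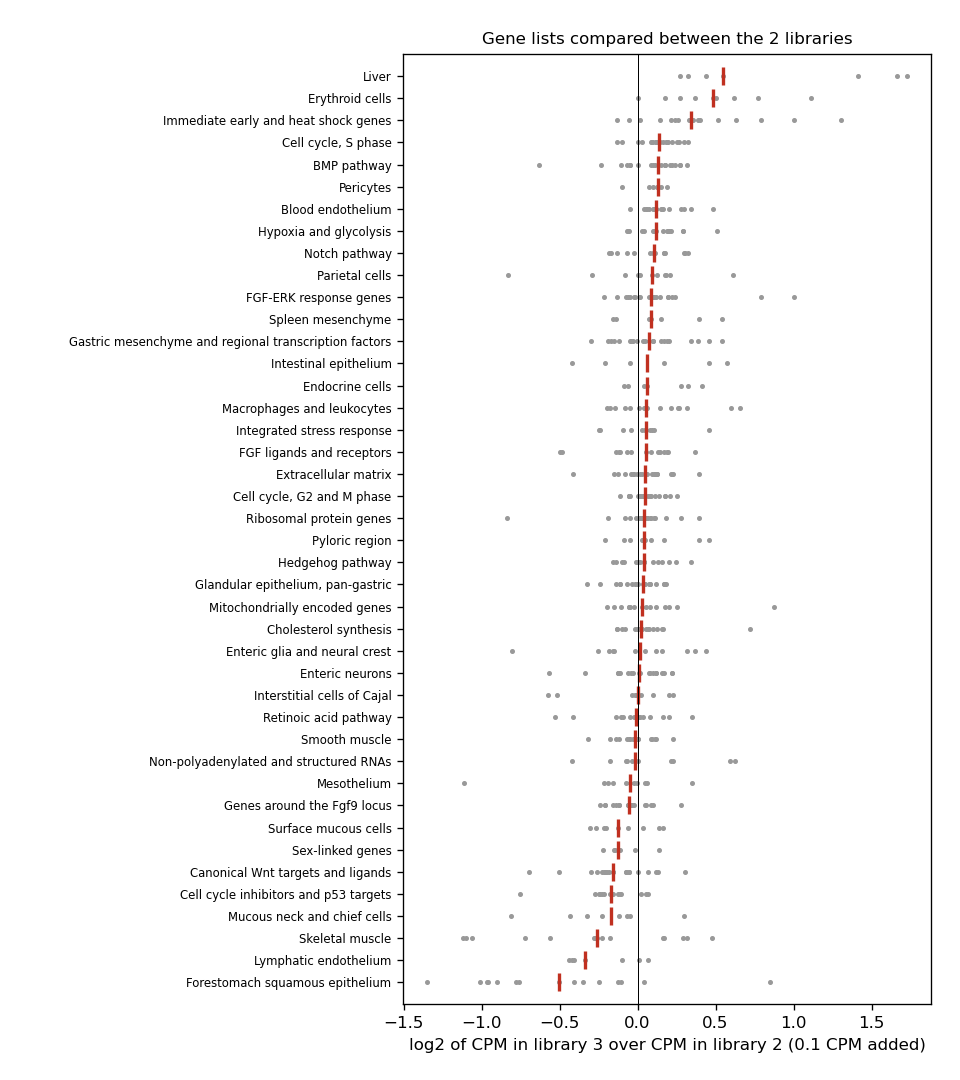
Gene lists compared between the 2 libraries, as log2 of CPM in library 3 over CPM in library 2 with 0.1 CPM added; grey points are list members with a mean of at least 1 CPM and red bars the list medians. The squamous list lies lowest and the liver, erythroid and immediate early lists highest, while most lists lie near 0.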

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

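The levels from the columns of a single label and the levels without structured RNAs were chosen after seeing the data. edgeR's count of 0 called genes stayed at 0 with RLE and upper-quartile factors, both other filters, limma-voom, the legacy method and both other thresholds. It also stayed at 0 without haemoglobin, mitochondrial and some non-coding genes, a setting that kept Gm26917 and Rn7s1. DESeq2 called 3 genes. With the replicate block, which pairs each library with itself, edgeR called 1178 genes at a median absolute log2 fold of 0.00597; the block changed no list's call. Leaving out 1 column gave 1 to 2 called genes by edgeR, among Rn7s6 and Gm19220, with the lone column assumed to vary like the other group. It gave 7 called lists by camera each time, the same 7 in each case, with directions that turned with the library left out; these contrasts set library 2 against library 3, whose genotypes are unresolved. camera with an estimated correlation, with RLE factors, with the stricter filter and with the block called 0 lists, as did fry in its directional and mixed forms. The log2 fold of Fgf9 was 0.000279 to 0.000801 over the other settings and -0.11 to 0.11 without 1 column.

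Of the 1188 fold values of named genes under other settings, 1174 kept their side of the threshold and 14 passed it, 13 of these for Rn7s6, Rn7s1, Gm19220 and Gm26461 and 1 for Malat1. Levels from the Fgf9_het columns alone were 1.007 to 1.008 times the reported ones, and those from the Fgf9_null columns alone 0.992 to 0.994 times, with 8 of 89 levels moved by more than 1 SD in each case. Without the structured and ribosomal RNAs, 79 of 89 levels moved by more than 1 SD, all by 1.20 to 1.21 times. Depth limits genes near the floor of 3 counts, and the named columns hold only 2 independent libraries, which limits every comparison.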

Other observations

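The tests of the duplicated columns, of Rn7s1 and of the joint expression of Xist and Y-linked genes were chosen after the result was seen. The tests of shared sequence and of carry-over were set before their results were seen.

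Genes of metabolism and of the cell's basic machinery were measured in both libraries as well. Srebf2, a regulator of cholesterol synthesis, stood at 304 ± 1.21 CPM (SD, n = 2 libraries). Ndrg1 and Ldha of the hypoxia and glycolysis list had 373 ± 21.0 and 293 ± 28.3 CPM. The mitochondrially encoded genes summed to 11020 ± 78.2 CPM, led by mt-Co1 at 3253 ± 77.6 CPM. Ribosomal protein genes summed to 8739 ± 147 CPM, led by Rplp0 at 1031 ± 3.65 CPM. Genes around the Fgf9 locus summed to 661 ± 16.6 CPM, with Zmym2 at 91.2 ± 2.79 CPM.

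The columns of the same replicate number matched across the genotype labels. Separate libraries of alike expression are argued against by the chi-square statistic per degree of freedom. Without Rn7s6, Rn7s1, Gm19220 and Gm26461 it was at most 0.00385, where separate draws of reads gave 1.00 in simulation. The value is consistent with reads of 1 library having been counted 2 times, once for each label. Which label the reads belong to stays open. With the same reads under both labels, the Fgf9 counts had to be nearly equal and could not decide it.

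Rn7s1 had 0.482 and 0.495 times as many reads under the Fgf9_het label as under the Fgf9_null label, and accounted for 98.9% and 98.6% of all reads lost between the columns. A genotype effect is argued against by the statistic of 0.00385 over the other genes, since the columns hold the same reads. The annotation holds 1 gene identical to Rn7s1 over its 300 bases, Rn7s2 (chromosome 12, 69361182 to 69361481), which has no row in the table used here; a candidate explanation is that 1 of the 2 counts divided reads between Rn7s1 and this identical gene. For the wider set of 15 genes that lost at least 5 reads in both libraries, 8 shared 31 bases with a gene without a row, against 8862 of 19945 others (odds ratio 1.43, 95% interval 0.453 to 4.63, two-sided Fisher exact p = 0.605). So few genes leave that open in either direction, although the bound set beforehand had counted any p of 0.05 or more against it. Gm19220 shared no such stretch. Of the 31-base stretches of Rn7s6 and Gm26461, 54.8% and 30.4% lay in Rn7s2. Rn7s6 has 0 identical genes, and its reads under the Fgf9_null label were 37.9 and 53.1 times those under Fgf9_het. A division of reads between 2 identical genes does not account for that difference, so the candidate explanation covers Rn7s1 only.

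The opposite set was larger in genes and smaller in reads. Under the Fgf9_het label 130 genes gained at least 5 reads in both libraries, and 51 of them (39.2%) shared 31 bases with a gene without a row. Over all genes, 9663 and 13942 reads were gained in replicates 2 and 3, against 277023 and 301493 reads lost.

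Xist, the RNA of the inactive X chromosome, stood at 1214 and 1042 CPM in libraries 2 and 3, where reads of its antisense gene Tsix may be included as no strand setting is given, together with the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. The lowest of these 5 genes in either library was Eif2s3y at 15.6 CPM, which restates the pattern and decides nothing between explanations. RNA of female and male embryos in each library may be the source, and so could carry-over of reads from a male library. The median of the Y-linked genes was 16.0% and 15.1% of their X-linked partners, above the 5% bound set beforehand for a small carry-over. Every pair lay above it, from 8.81% for Ddx3y in library 3 to 37.4% for Uty in library 2. These values argue against a small carry-over in both libraries, although the bound assumed a ratio for male stomach. No library here is labelled by sex, so a larger carry-over and RNA of both sexes cannot be told apart. No biological explanation from the design was tested, as the genotype of the libraries is unresolved.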
